A study of Mus musculus with 8 samples.

How the data were processed

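The deposited table holds 768 probes of a NanoString nCounter mouse panel in 8 samples: 754 genes, 6 positive controls and 8 negative controls. The labels' protocols describe pooling of 3 lungs per sample, enzymatic dissociation, bead isolation by CD11b and CD11c and column purification of RNA. The software used to make the values is not given in the sources used here. The values were deposited by the authors on a log2 scale with 2 decimals. Their scaling was worked out from the values. Control probes were unscaled whole counts, and the low values of each gene column (under 40 counts) were all whole multiples of 1 step within 0.0076 on the log2 scale, close to the factor given by 5 of the positive controls. The deposited gene values therefore carry a spike-in factor per sample, between 0.605 and 6.84, and no scaling to housekeeping genes or to the panel. Such values move with the amount of RNA loaded and with any error in the spike-in counts. Counts recovered by removing the factor are exact only for low values, since 2 decimals round the bright ones. In all, 3 values were listed at 0.

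A gene counted as above background in a sample where its recovered count exceeded the mean plus 2 SD of the negative controls, a limit of 18.0 to 40.0 counts. Depth differed between samples, and the gene values of DSHN 1 are the least precise. Gene symbols were used as deposited: 744 matched the symbols of the GRCm38.p6 gene table, 9 a synonym and 1 neither. Nr0b2 and Foxp3 were not analysed here. Each sample is a pool from separate animals and counted as 1 replicate.

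The main test was set before the data were examined: limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a variance trend, DSHN against DMSO without covariates, on genes with a value of 20 or more in at least 4 samples (554 genes), and Benjamini-Hochberg adjustment at 0.05. Gene lists for 35 pathways and cell types were also fixed then, of which 29 had at least 5 tested members; they were tested with limma camera at an inter-gene correlation of 0.01. The design took the deposited values to be comparable between samples. Once the shift of the whole panel was seen, named genes and lists were reported on values scaled to the geometric mean of the 4 housekeeping genes at 100 or more in every sample. This scaling had been named beforehand as a check, and reporting on it was chosen after seeing the data. It assumes that these 4 genes did not themselves respond to treatment. P-values of single sample measures are from exact permutation over 70 assignments.

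Named genes followed a rule fixed beforehand: up to 12 genes per direction past the threshold, filled to 6 by smallest unadjusted p where fewer passed; Nr0b2, Il1b, Il18, Nlrp3, Casp1, Foxp3, Itgam and Itgax where measured; and up to 4 members with the smallest p of each list described, of which up to 2 were named. The rule was applied on the deposited scale and, after the data were seen, on the housekeeping scale. For some genes that the rule picked, the result is not reported here. Other settings named beforehand were other filters, median centring, quantile normalization, housekeeping scaling, a replicate block, sample weights, other variance models, an exact permutation test per gene, leaving out each sample, an estimated inter-gene correlation and fry. A pseudocount did not apply to log values, and count models were not run because bright counts are known only to rounding. Settings added after seeing the data left out DMSO 1 and DSHN 1 together, combined housekeeping scaling with other choices, scaled to 11 housekeeping genes or to 3 (Tubb5 left out), subtracted background, removed the spike-in factor, ran voom on recovered counts, and estimated sample weights gene by gene, since limma's default estimation stopped before it converged. The inter-gene correlation was also estimated in the fits without 1 sample, without DMSO 1 and DSHN 1, with sample weights, without the spike-in factor, with 3 housekeeping genes and after median centring. With all 8 samples, camera in that variant gave adjusted p = 0.999 for every list as deposited. Relative to housekeeping genes it gave 0.909 or 0.92 for every list. That variant was not run on simulated data and was not shown able to call a list here. A call that it does not keep is therefore left undecided. No difference is given for a gene above background in 0 samples of a group.

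The code was tested on simulated data with the real gene means, sample shifts and spread, 554 genes of which 200 were changed, in 20 runs. For DSHN against DMSO relative to housekeeping genes, 50.4% of changes of 1 on the log2 scale and 89.3% of changes of 2 were recovered, with 1.33% of unchanged genes called. On the deposited scale 34.7% and 49.4% were recovered, with 3.43% of unchanged genes called. The estimates there carried the shift of the samples, with a mean of -0.91 for a change of 1. Lists were tested on separate simulated values without sample shifts, where only the MHC class I list was raised, by 1, and that list was called in 20 of 20 runs. Noise was drawn independently for each gene, so these runs do not show how often a list would be called among correlated genes. It was also alike in all samples, with no sample profile set apart as in DMSO 1 and no background floor as in DSHN 1. With 200 of 554 genes changed, the adjusted threshold is easier to reach than with few. The recovered shares are therefore a check of the code and not the power of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.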

Results

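Expression of a panel of 754 mouse immune genes was measured with NanoString nCounter, an assay that counts colour-coded probes bound to RNA without amplification, in myeloid cells taken from lungs of Balb/c mice grafted with 4T1 cells, a mouse mammary carcinoma line that spreads to the lung. The 24 mice received either DMSO as placebo or DSHN, an agonist of the nuclear receptor NR0B2, at 10 mg/kg daily for 7 days, starting 10 days after the graft. Lungs of 3 mice of the same treatment were pooled per sample, and cells were isolated with beads against CD11b and CD11c, which gave 4 DMSO and 4 DSHN samples from separate animals. The comparison is DSHN against DMSO, and it addresses what activating NR0B2 does to myeloid cells of lungs exposed to a spreading mammary tumour.

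The most abundant transcripts were those of myeloid cells. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils and monocytes, together made up 17.8 ± 4.02% of all gene counts in DMSO samples and 18.6 ± 4.32% in DSHN samples (SD, n = 4 each), a difference smaller than the SD of either group. Ctsd, a lysosomal protease, Tyrobp, a signalling adaptor of myeloid receptors, and Il1b, the cytokine interleukin 1 beta, were also among the 7 highest genes. Recovered counts summed over the gene probes ranged from 533300 to 923800 in 7 of the samples and were 123700 in DSHN 1. In DSHN 1, 293 of the 754 genes lay above the background set by the negative-control probes, against 498 to 559 in the other samples. The spike-in control counts of DMSO 1 were low, with a geometric mean of 562.6 against 3281 to 6392 elsewhere, and its deposited gene values had been multiplied by 6.84.

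**Figure D1:**
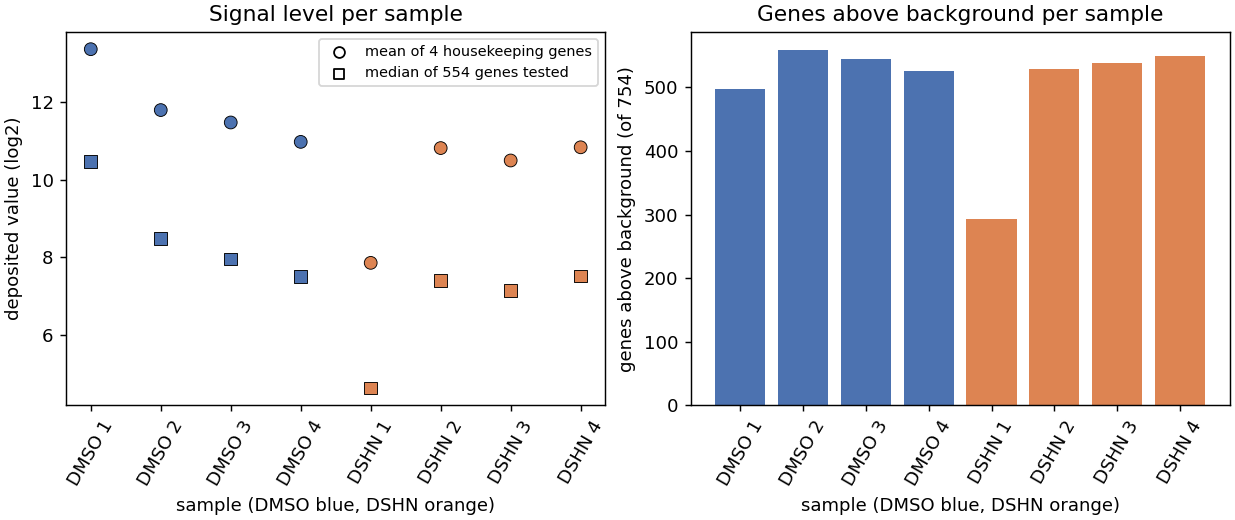
Left, mean deposited log2 value of the 4 housekeeping genes (circles) and median deposited log2 value of the 554 genes tested (squares) in each sample; right, number of the 754 genes above background in each sample, with DMSO samples in blue and DSHN samples in orange. DMSO 1 has the highest panel median, 10.48, and DSHN 1 the lowest, 4.63, together with the fewest genes above background, 293.

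In the values as deposited, nearly the whole panel was lower in DSHN samples. Of the 554 genes tested, 553 had a lower mean in DSHN and 1, Lamp3, a marker of mature dendritic cells, had a higher mean, by 0.41 on the log2 scale. The median difference over these genes was -1.87. The 4 housekeeping genes Oaz1, Ppia, Rpl19 and Tubb5 shared it: their mean was 11.91 ± 1.03 in DMSO and 10.01 ± 1.44 in DSHN (SD, n = 4 each), a difference of -1.90 (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). The panel median per sample differed by -1.93, with p = 0.0571 in the same permutation test. No gene passed the threshold in limma with Benjamini-Hochberg adjustment (0 of 554, lowest adjusted p = 0.127), while 196 genes, all lower, were counted at an unadjusted p under 0.05. That count was 7 without DSHN 1, 23 without DMSO 1, 60 without DMSO 2, 72 without DSHN 3 and 121 without DMSO 3. It was 136 without DSHN 2, 196 without DSHN 4 and 274 without DMSO 4. Without both DMSO 1 and DSHN 1 it was 139, of which 138 were lower. It was 6 with a replicate block, 17 after median centring, 16 after quantile normalization, 25 with the spike-in factor removed and 240 without a variance trend. In the main fit limma took each variance as known from the trend, with no allowance for the few samples per group. The genes also carry a shared shift, so the 196 are not a count of separate gene effects. Among the genes with the smallest p were Cd40, Il15, Usp18 and H2-Ob, with log2 differences of -2.30, -2.29, -2.21 and -2.03, and Vrk2, a kinase whose transcript was above background in 0 of 4 DSHN samples, so that no difference is given. Cd40 is a costimulatory receptor, Il15 a cytokine that sustains NK and memory T cells, Usp18 an interferon-induced protease and H2-Ob a modulator of MHC class II loading. Relative to the housekeeping genes the differences were -0.40 for Cd40, -0.39 for Il15, -0.30 for Usp18 and -0.12 for H2-Ob, and each turned in sign without DMSO 1, to 0.10, 0.02, 0.56 and 0.01. H2-Ob also did so without DSHN 2 (0.06) or DSHN 4 (0.11), and as it was above background in 1 of 4 DSHN samples, the size of its difference is not known. The exact permutation test per gene also gave 0 genes after adjustment and 226 before it. When samples were weighted by their estimated variability, 271 genes passed, 269 of them lower, and the median difference was -0.71. That weighting gave DMSO 1 a weight of 0.058 and DSHN 1 a weight of 0.0553, and its estimation stopped before it converged. Estimated gene by gene, without such a warning, the weights gave 320 genes, 319 of them lower.

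Because the housekeeping genes carried the same shift as the panel, gene differences are given from here on relative to those 4 genes, after which the median difference over the 554 genes was 0.03 and 296 genes were higher and 258 lower in DSHN. Each gene's difference on the deposited scale is this difference with the same shift of -1.90 added, so a gene that is higher by less than that shift is lower there. No gene passed the threshold on this scale either (0 of 554 in limma, lowest adjusted p = 0.925). At an unadjusted p under 0.05 there were 20 genes, 17 higher and 3 lower, where 27.7 are expected by chance, and 11 without DSHN 3 or 12 without DSHN 1. With background subtracted there were 12, 7 higher and 5 lower. Among the 291 genes above background in all 8 samples there were 4, 2 higher and 2 lower. Of the 4 housekeeping genes, Tubb5 lay at -1.40 in DMSO 1 from the mean of the other 7 samples, and Oaz1, Rpl19 and Ppia at 0.60, 0.55 and 0.26. With Tubb5 left out of the scaling, the median difference was 0.20, 0 genes passed and 25, all higher, were counted at an unadjusted p under 0.05. Limma's voom on the recovered counts gave 0 genes after adjustment and 14 before it. With sample weights, 5 genes passed, Csf2, Lamp3, Il13, Cdh5 and Cxcl13, all higher, again with an estimation that stopped early. Weights estimated gene by gene left 1, Csf2, at 1.46 (adjusted p = 0.0274).

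Csf2, which encodes the growth factor GM-CSF, was higher in DSHN by 1.51 ± 0.37 (log2, SE), with 5.59 to 5.99 in the 3 DSHN samples and 4.19 to 4.70 in the 2 DMSO samples where it was above background. In DSHN 1, DMSO 1 and DMSO 4 it lay under background, and on the deposited scale its difference was -0.39. Lamp3 was higher by 2.31 ± 0.62, and by 1.42 without DMSO 1 and DSHN 1. The type 2 cytokine Il13 was higher by 1.64 ± 0.48, Tspan7 by 1.60 ± 0.53 and Cdh5, an endothelial cadherin, by 1.50 ± 0.51. All of these lay near background: Csf2, Lamp3 and Il13 were above it in 2 of 4 DMSO and 3 of 4 DSHN samples, Tspan7 in 3 and 3, and Cdh5 in 1 and 3, so that the size of its difference is not known. Without DMSO 1 and DSHN 1, Il13 was higher by 1.25 and Tspan7 by 0.88. Alas1, an enzyme of haem synthesis that was above background in all 8 samples, was higher by 0.59 ± 0.21. Il13, Tspan7, Cdh5 and Alas1 had deposited differences of -0.26, -0.30, -0.40 and -1.31, through the shift common to all genes. None of these genes passed the threshold.

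Among the genes lower in DSHN, 3 were counted at an unadjusted p under 0.05, Atf3, Casp1 and Dusp1. Atf3, a stress-induced transcription factor, was lower by -0.60 ± 0.21 (log2, SE), with 10.63 to 11.06 in the DSHN samples and 11.17 to 11.85 in the DMSO samples. Dusp1, a phosphatase acting on MAP kinases, was lower by -0.62 ± 0.27, the protease Ctss by -0.64 ± 0.32, the surface receptor Cd84 by -0.47 ± 0.22 and Cebpa, a transcription factor of myeloid differentiation, by -0.47 ± 0.23. Without DMSO 1 the difference was -0.38 for Dusp1 and -0.28 for Cd84, without DSHN 1 it was -0.35 for Ctss, and without DMSO 4 it was -0.30 for Cebpa. Without both DMSO 1 and DSHN 1 it was -0.30 for Dusp1 and -0.24 for Ctss. None of these 5 genes passed the threshold, and all were above background in all 8 samples.

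Of the inflammasome and interleukin 1 genes, 8 of 12 tested were higher and 4 lower in DSHN, with a median difference of 0.11 and a mean of 0.02, while camera placed the list slightly below the rest of the panel (adjusted p = 0.887). Il1rl1, the receptor for interleukin 33, differed by 0.39 ± 0.35, by 0.20 without DMSO 3 or DSHN 1, and by -1.51 on the deposited scale. Casp1, the protease that matures interleukin 1 beta, was lower by -0.54 ± 0.23, with 7.44 to 7.74 in the 3 DSHN samples where it was above background and 7.78 to 8.51 in DMSO samples, and by -0.28 without DMSO 1 and DSHN 1. Il1b differed by -0.33 (95% interval -1.31 to 0.64), by 0.00 without DMSO 1 and by 0.21 without DMSO 1 and DSHN 1. Il18 differed by 0.29 (-0.56 to 1.14) and the inflammasome sensor Nlrp3 by 0.09 (-0.50 to 0.68), and both were lower on the deposited scale, by -1.61 and -1.81. Without DMSO 1, Il18 differed by -0.11, and Nlrp3 differed by -0.07 without DMSO 4 and -0.01 without DSHN 2. Itgam and Itgax, which encode the CD11b and CD11c chains used for isolation, differed by -0.37 (-1.61 to 0.87) and 0.41 (-0.59 to 1.42); without DMSO 1 both signs turned, to 0.25 and -0.09, as they did without DMSO 1 and DSHN 1, to 0.20 and -0.03. Itgax was also lower on the deposited scale, by -1.49. None of these genes passed the threshold.

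**Figure D2:**
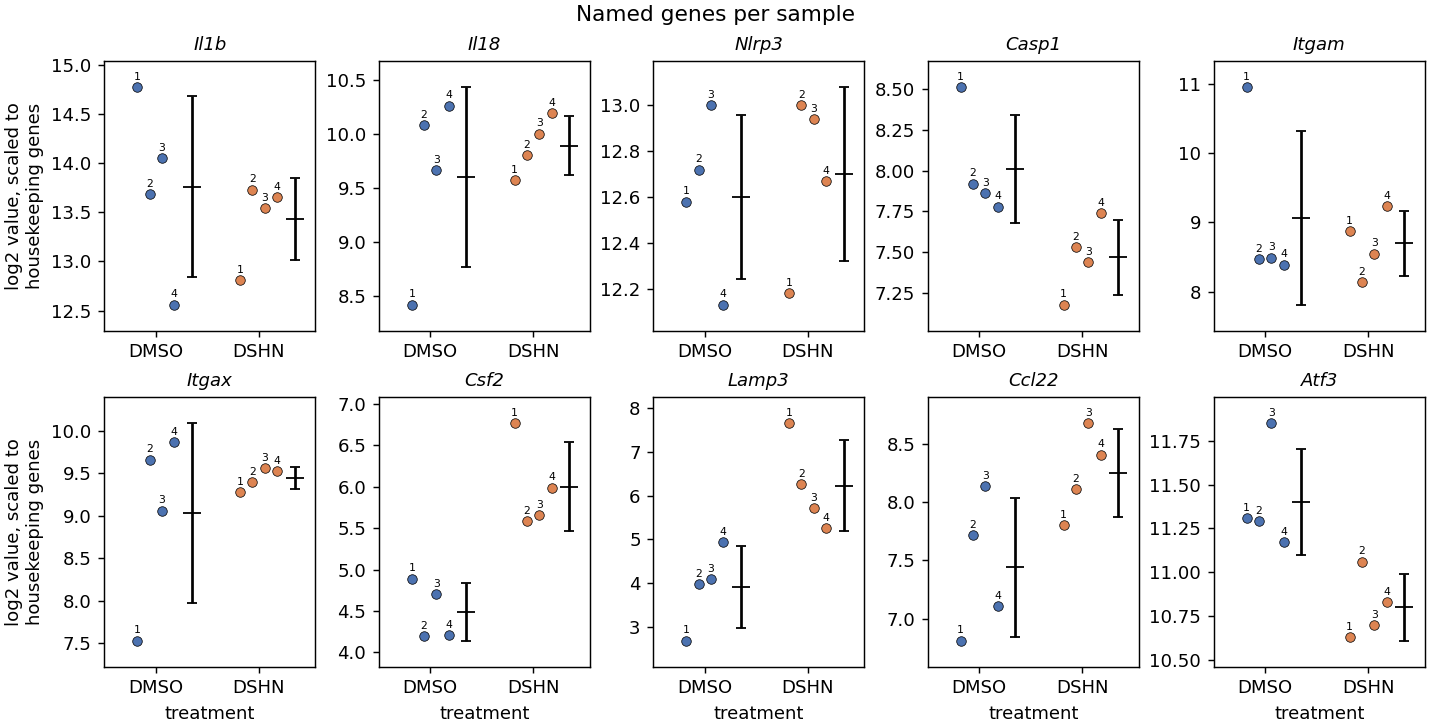
Log2 values scaled to the housekeeping genes for 10 named genes in each sample (points, numbered by replicate; DMSO blue, DSHN orange), with mean and SD of each group of 4 in black. Atf3 is lower by -0.60 with no overlap between groups, and Csf2, under background in DSHN 1, DMSO 1 and DMSO 4, is higher by 1.51, or -0.39 on the deposited scale, with neither past the threshold; DMSO 1 stands apart for Itgam at 10.96 and Itgax at 7.53.

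The gene lists fixed beforehand were compared with the rest of the panel. As deposited, 1 of 29 lists passed the threshold, that of eosinophil genes, whose 8 members were lower in DSHN by a median of -1.27 but less so than the rest of the panel (limma camera, adjusted p = 0.0231; adjusted p = 0.999 with an estimated correlation). Relative to the housekeeping genes 7 of the 8 were higher, with a median difference of 0.63, and the list did not pass (adjusted p = 0.128). Il13 and the eotaxin receptor Ccr3, at 0.70 ± 0.55 and -1.20 as deposited, were its members with the smallest p, and Ccr3 differed by 0.16 without DSHN 1. The mean of the list was 8.61 in DSHN 1 and 6.33 to 7.58 in the other samples. The deposited call was lost without DMSO 1 (adjusted p = 0.736), without DSHN 1 (0.732) and without DSHN 3 (0.103), while without DSHN 4 it was stronger (9.36e-05; adjusted p = 0.994 with an estimated correlation). Relative to the housekeeping genes the list passed without DSHN 4 (0.0286; adjusted p = 0.832 with an estimated correlation). On deposited values without both DMSO 1 and DSHN 1 the list lay below the rest of the panel (0.466).

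Relative to the housekeeping genes, 0 of 29 lists passed, with a lowest adjusted p of 0.0629. That value was shared by 4 lists: endothelial genes (6 of 6 higher, median 0.48), T cell genes (5 of 5 higher, 0.62), MHC class I genes (3 of 14 higher, -0.29) and Fc receptor and phagocytosis genes (4 of 15 higher, -0.20). With an estimated correlation, adjusted p = 0.909 for each of these 4, and 0.909 or 0.92 for every list, so that variant set no list apart. Without DMSO 1 and DSHN 1 the medians were 0.35, 0.38, -0.05 and -0.04. After median centring, which had been set as a check beforehand, MHC class I genes passed (adjusted p = 0.022; adjusted p = 0.857 with an estimated correlation), as they did with Tubb5 left out of the scaling (0.0447; adjusted p = 0.856 with an estimated correlation). Several lists passed when 1 sample was left out. Endothelial genes did so without DMSO 3 (0.0363), DMSO 4 (0.0445), DSHN 1 (0.0471) or DSHN 4 (0.0425), and T cell genes without DMSO 3 (0.0363) or DSHN 4 (0.043). Fc receptor and phagocytosis genes did so without DMSO 1 (0.0464), DMSO 3 (0.0363) or DSHN 4 (0.0286), and MHC class I genes without DMSO 4 (0.0143) or DSHN 4 (0.043). With an estimated correlation in the same fits none of these calls held, with adjusted p from 0.431 to 0.967. Cdh5 and Cd34, at 1.23 ± 0.57, led the endothelial list, and Cd247, a chain of the T cell receptor complex, at 1.42 ± 0.53, led the T cell list. Without DSHN 1 the difference was 0.69 for Cd34 and 0.89 for Cd247. All 3 genes were lower on the deposited scale, Cd34 by -0.68 and Cd247 by -0.48. The inhibitory receptor Lag3, above background in 0 of 4 DMSO and 1 of 4 DSHN samples, was too close to background for a difference to be given. None of the T cell genes and 1 of the endothelial genes lay above background in all 8 samples. H2-K1, an MHC class I heavy chain, differed by -0.52 ± 0.32 and Calr, a chaperone of its assembly, by -0.37 ± 0.26, and without both DMSO 1 and DSHN 1 by -0.11 and -0.04. H2-K1 differed by -0.22 without DMSO 1 and Calr by -0.15 without DSHN 1. In the Fc receptor and phagocytosis list, the macrophage marker Cd68 differed by -0.52 ± 0.28 and the receptor Fcgr1 by -0.99 ± 0.71, with -0.28 for Cd68 without DSHN 1 and -0.14 for Fcgr1 without DMSO 1. With all 8 samples, 0 members of each of the 29 lists passed when adjusted over the list alone and 0 when adjusted over all genes tested. Without DMSO 1 and DSHN 1, Il13 in the eosinophil list (1.25, adjusted p = 0.015) and the kinase Ikbke in the NF-kB and TNF list (0.87, 0.0198) passed when adjusted over the list alone, and 0 genes over all genes tested.

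Genes tied to regulatory T cells through the myeloid compartment were considered because the title of the series names regulatory T cell expansion. In the list of suppressive genes, 6 of 17 were higher and 11 lower, with a median of -0.10 and a mean of 0.02, on the other side of 0. Without DMSO 1 and DSHN 1, 12 of the 17 were higher, with a median of 0.26. Ccl22 and Ccl17, chemokines that attract CCR4-bearing T cells, differed by 0.81 ± 0.33 and 0.60 ± 0.37, and both were lower on the deposited scale, by -1.09 and -1.31. Ccl17 differed by 0.38 without DSHN 3. Chemokines as a list had 7 of 23 members higher and a median of -0.19, and without DMSO 1 and DSHN 1 21 higher and a median of 0.35. In that comparison DMSO 4 had the lowest list mean, 7.34 against 8.02 to 8.39 in the other samples used. Cxcl13, a B cell attractant, differed by 1.02 ± 0.43, and by -0.88 on the deposited scale. The chemokine list passed as lower without DMSO 4 (adjusted p = 0.0445), as did complement genes (0.0143), of which 0 of 7 were higher over all samples, with a median of -0.31. With an estimated correlation neither call held (adjusted p = 0.878 for both). On deposited values the chemokine list passed as higher than the rest of the panel, nearly all of which was lower in DSHN. It did so without DMSO 1 (0.0342), without DSHN 1 (0.0235), with sample weights (0.0364) and with weights estimated gene by gene (0.0113). With an estimated correlation none of these calls held (adjusted p from 0.982 to 0.993). Relative to the housekeeping genes, without DMSO 1 and DSHN 1 all 7 complement genes were higher, with a median of 0.32. The complement list mean was 8.81, 8.86 and 7.65 in DMSO 2, 3 and 4 and 8.72, 8.48 and 9.21 in DSHN 2, 3 and 4, so this too leaned on DMSO 4. MHC class II genes had 1 of 10 higher, with a median of -0.17, and the protease Ctsl at -0.95 ± 0.82, or 0.01 without DMSO 1, and the list passed as lower without DMSO 1 (0.0193), DMSO 4 (0.0143) or DSHN 4 (0.042). With an estimated correlation these calls were lost (adjusted p = 0.967, 0.878 and 0.832), and without DMSO 1 and DSHN 1 6 of the 10 were higher, with a median of 0.02. Type I interferon genes had 2 of 10 higher, with a median of -0.25 and Siglec1, a sialic acid receptor of macrophages, at -0.47 ± 0.37, or -0.08 without DMSO 1. Without DMSO 1 and DSHN 1, 6 of the 10 were higher, with a median of 0.19. Neutrophil genes (6 of 15 higher, median -0.02) and alveolar macrophage genes (5 of 10 higher, median 0.00) lay close to 0, with Ceacam1 at -0.61 ± 0.41, Fpr1 at 0.34 ± 0.25, or -1.56 as deposited, and Ctsd at -0.36 ± 0.25. Ceacam1 was at -0.20 without DMSO 1, Fpr1 at 0.15 without DMSO 3 and Ctsd at -0.22 without DSHN 1. Alveolar macrophage genes passed as lower without DMSO 1 (0.00186; adjusted p = 0.967 with an estimated correlation). Costimulation and dendritic cell maturation genes had 9 of 17 higher and a median of 0.05, with Socs2, an inhibitor of cytokine signalling, at 0.39 ± 0.28, or 0.17 without DMSO 1 and -1.51 as deposited. None of these genes passed the threshold.

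**Figure D3:**
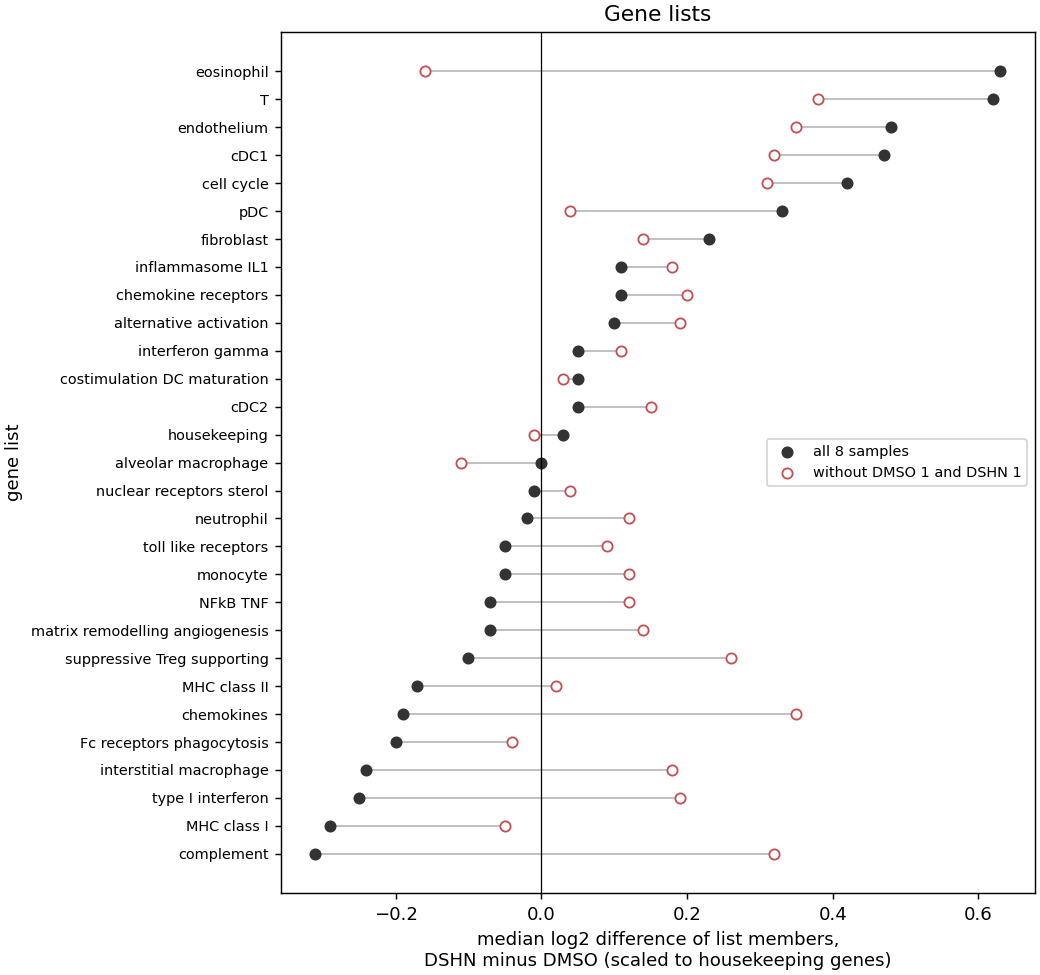
Median log2 difference, DSHN minus DMSO and scaled to the housekeeping genes, of the members of each of 29 gene lists (vertical axis) over all 8 samples (filled) and without DMSO 1 and DSHN 1 (open). The median of the chemokine list goes from -0.19 to 0.35 and that of the eosinophil list from 0.63 to -0.16; 0 lists passed with all 8 samples.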

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

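The tests of explanations in this part were chosen after the results were seen, except the counts of sample splits for unweighted values. Of 94 groups of 4 values checked, 14 had 1 sample far from the other 3, where chance flags about 1 in 20. The groups are measures of the same samples and not independent, so 14 is no test against that rate. DMSO 1 was the sample set apart in 7 and DSHN 1 in 6.

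The first pattern is the lower level of the whole panel in DSHN samples as deposited. DSHN 1 stood far below the other DSHN samples in housekeeping mean (7.86 against 10.50 to 10.84), panel median (4.63 against 7.14 to 7.52), genes above background (293 against 529 to 549) and recovered total count (123700 against 533300 to 617700), and DMSO 1 had a log2 spike-in factor of 2.77 against -0.09 to 0.22. After scaling to the housekeeping genes the median difference was 0.03 with a standard error between samples of 0.15, that is, housekeeping genes and panel moved alike. Unequal RNA content between samples or the spike-in factors would move them alike, and a treatment effect shared by housekeeping and other genes would too and stays open. The mean log2 spike-in factor was itself lower by -1.10 in DSHN, and the deposited values carry that difference. Before the factors were applied, DMSO 1 had a panel median of 7.70 against 7.58 to 8.26 in the other DMSO samples, so its high deposited level came from its factor. On deposited values without DMSO 1, with the factors of the other samples kept, the median difference was -1.28 with a standard error of 0.74. Without the spike-in factors of all 8 samples it was -0.77 with 0.57. What is left once the factors are removed cannot be told apart from sample spread, and whether the factor of DMSO 1 is an error was not tested.

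The 196 genes at unadjusted p under 0.05 were reached by 1 of 35 splits of the samples, the real one, with 193 as the highest of the others. All 15 splits with DMSO 1 and DSHN 1 on the same side gave 0 genes, and 18 of the 20 with them apart gave more than 0, so across splits the count followed where those samples fall. With both left out the real grouping still gave 139 genes, 138 of them lower, with a median difference of -0.64. Those 2 samples therefore do not account for all of it, and other groupings were not run without them. For the 1 list past the threshold 33 splits gave as many (highest other 8), so chance is not excluded. For the 0 genes past the threshold all 35 splits necessarily reach the count (highest other 1), which decides nothing. With sample weights, 4 of 35 splits gave 271 genes or more, the highest other 533, which points to a structure of the samples and does not exclude chance.

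The second pattern is DMSO 1, singled out by its spike-in factor, which lay apart from the other samples relative to the housekeeping genes. It lay far from the other DMSO samples for Itgam (10.96 against 8.39 to 8.49 in the other DMSO samples), Ctsl (12.64 against 8.59 to 9.04), Fcgr1 (11.15 against 7.49 to 8.10), Siglec1 (8.36 against 6.66 to 6.89), Cd40 (7.18 against 4.98 to 5.31) and Cd84 (10.70 against 9.87 to 9.99). A factor common to the whole lane moves all genes alike and is removed by this scaling, so it leaves unexplained that the neutrophil list and the alveolar macrophage list were displaced apart by 1.71, with a standard error over genes of 0.45. A larger share of neutrophil and a smaller share of alveolar macrophage transcripts may be part of it. The neutrophil list lay 1.03 above and the alveolar macrophage list -0.68 (standard error over genes 0.40) from the mean of the other 7 samples. With Tubb5 left out of the scaling these were 0.56 and -1.15. Such list means describe 1 sample and restate the pattern, so they do not test that reading. S100a8 was 17.15 against 15.10 to 16.46, and 13 of 15 neutrophil genes were higher in DMSO 1. Fpr1 (-0.03) and Cxcr1 (-0.76) were not. The S100a8 and S100a9 share of counts, 23.1%, was close to the 22.7% of DSHN 4. Complement genes (median 2.10) and interstitial macrophage genes (2.09) were displaced further than neutrophil genes (1.31), so those shares of transcripts leave much of the pattern open. Whether isolation or the animals changed the shares was not tested.

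The third pattern is that 17 genes at unadjusted p under 0.05 were higher in DSHN relative to the housekeeping genes. Of these, 15 lay under background in DSHN 1, and only 2 were above it there. The median difference of the 17 genes was 1.27, 0.95 without DSHN 1, and 1.45 without DSHN 1 and with background subtracted. Background counts in DSHN 1 stay open as a candidate explanation, because only 4 of the 17 were above background in all 7 other samples and subtraction near the floor sets such values. For the 20 genes in both directions, 16 of 35 splits gave as many, the highest other 62, so chance is not excluded.

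Vrk2 in DSHN 1 was 5.70 against 3.93 to 4.20 in the other DSHN samples. Usp18 in DSHN 1 was 5.96 against 4.90 to 5.08. Both values of DSHN 1 lay under its background limit of 7.69 on this scale, so neither is a measured level. Cxcl13 in DSHN 4 was 5.99 against 7.48 to 7.65.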

How the results depend on the processing

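The settings that leave out DMSO 1 and DSHN 1 together, combine housekeeping scaling with another choice, use 11 or 3 housekeeping genes, subtract background, remove the spike-in factor, use voom or estimate weights gene by gene were chosen after the results were seen, as was leaving out samples on the housekeeping scale. The cause of the changes below was not tested. Count models were not run. The number of genes past the threshold stayed 0 without any 1 sample and under the other settings except weights: 271 with sample weights, 320 with weights estimated gene by gene, 5 with sample weights and 1 with gene-by-gene weights relative to housekeeping genes. The default estimation of the weights stopped before it converged. A replicate block gave 0 genes, 6 at an unadjusted p under 0.05, and 1 list. The labels do not say that sample numbers pair samples. The correlation across genes between same-numbered samples of the 2 groups was -0.29 to 0.14, against -0.33 to 0.32 for other pairs. These few values show no pairing and cannot exclude it. Lists past the threshold were 0 with no filter on low values, with the filter at 100, after quantile normalization, with an estimated correlation, with fry and relative to housekeeping genes (alone, with a replicate block, with either kind of weights, in genes above background, or with 11 genes). They were 2 with sample weights of either kind (chemokines higher, and MHC class II lower at 0.0117 and 0.0113), with the spike-in factor removed (endothelial genes at 0.0264 and eosinophil genes at 0.0415, both higher), or on deposited values without DMSO 1 and DSHN 1 (chemokines, and alternative activation at 0.00963, both higher). Higher and lower are here relative to the rest of the panel, most of which was lower in DSHN in these fits. None of these calls held with an estimated correlation (adjusted p from 0.982 to 0.992), a variant not shown able to call a list here. Without 1 sample they ranged from 0 to 5, and from 0 to 6 relative to housekeeping genes. The median difference ranged from -2.21 to -1.24 without 1 sample, and from -0.05 to 0.13 relative to housekeeping genes. It was 0.03 with housekeeping scaling and with a replicate block added, 0 with sample weights and 0.01 with gene-by-gene weights added, 0.06 without DMSO 1 and DSHN 1, -0.08 in genes above background, -0.20 with background subtracted, -0.01 with 11 housekeeping genes, 0.20 with 3 housekeeping genes, -0.64 on deposited values without DMSO 1 and DSHN 1, 0.06 with median centring, -0.02 with quantile normalization and 0.01 with voom.

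Vrk2 and Lag3 were above background in 0 samples of a group and get no value here. Of the other 38 named genes, 17 had the opposite sign on the deposited scale, where all genes carry the same shift of -1.90, so these turns say nothing about single genes: Csf2 -0.39, Il13 -0.26, Tspan7 -0.30, Cdh5 -0.40, Alas1 -1.31, Il18 -1.61, Nlrp3 -1.81, Itgax -1.49, Il1rl1 -1.51, Ccl22 -1.09, Ccl17 -1.31, Cxcl13 -0.88, Socs2 -1.51, Fpr1 -1.56, Cd247 -0.48, Cd34 -0.68 and Ccr3 -1.20. Sample weights turned Usp18 0.44, Il18 -0.05, Itgam 0.08 and Itgax -0.07, and gene-by-gene weights Usp18 0.38, Il18 -0.02, Itgam 0.06 and Itgax -0.03. Leaving out DMSO 1 and DSHN 1 turned Usp18 0.32, Il1b 0.21, Itgam 0.20, Itgax -0.03 and Ctsl 0.34. Quantile normalization turned Il1rl1 -0.02 and background subtraction Il1rl1 -0.54 and Ccl17 -0.27, and 3 housekeeping genes H2-Ob 0.05. Without 1 sample, signs turned within Cd40 -0.66 to 0.10, Il15 -0.61 to 0.02, Usp18 -0.69 to 0.56, H2-Ob -0.54 to 0.11, Il18 -0.11 to 0.50, Nlrp3 -0.07 to 0.26, Itgam -0.60 to 0.25, Itgax -0.09 to 0.69 and Ctsl -1.34 to 0.01. Background limits the low genes most in DSHN 1, where its limit relative to housekeeping genes was 7.69 against 3.77 to 5.12 elsewhere.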

Other observations

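The comparisons in this part were chosen after seeing the data. Without DMSO 1 and DSHN 1, chemokine genes were higher in DSHN than the rest of the panel relative to the housekeeping genes (limma camera, adjusted p = 0.000246; adjusted p = 0.763 with an estimated correlation), with 21 of 23 members higher and a median difference of 0.35, and 6 members at an unadjusted p under 0.05. The eosinophil and macrophage chemoattractants Ccl24 and Ccl8 differed by 1.43 and 1.71 there, Ccl22 by 0.75 and Cxcl13 by 1.14. The list mean in this comparison was 8.02, 8.10 and 7.34 in DMSO 2, 3 and 4 against 8.24 to 8.39 in the DSHN samples, so DMSO 4 made up much of the difference. No member passed when adjusted over the list alone (0) or over all genes (0). With all 8 samples the list lay lower (adjusted p = 0.571), and without DMSO 4 lower past the threshold (0.0445; adjusted p = 0.878 with an estimated correlation). On deposited values it passed as higher than the rest of the panel, nearly all of which was lower in DSHN, without DMSO 1 (0.0342) and without DSHN 1 (0.0235). An estimated correlation did not keep these calls (0.99 and 0.993). The direction of the list relative to the panel rested on which samples were used. Over the settings run, its adjusted p ranged from 4.36e-07 to 0.999.

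In DMSO 1, relative to the housekeeping genes, Arg1, an enzyme of arginine breakdown, was 14.58 against 6.02 to 9.36 in the other 7 samples, Ccl24 was 11.41 against 4.98 to 7.68 and the complement gene C1qa 10.28 against 6.70 to 8.77. Type I interferon genes lay above the mean of the other samples by a median of 1.45, with 10 of 10 higher, and eosinophil genes at -1.09, with 1 of 8 higher. The 20 genes of the housekeeping list had a median of 0.01, but Tubb5, 1 of the 4 used for scaling, lay at -1.40. With Tubb5 left out of the scaling the medians were 0.99 for type I interferon genes, -1.56 for eosinophil genes and -0.46 for the housekeeping list. Itgax was 7.53 there against 9.06 to 9.87 elsewhere, and Siglecf, a marker of alveolar macrophages and eosinophils, 6.17 against 7.93 to 9.02. These genes were named after their values were seen.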
